A study of Naumovozyma castellii with 14 samples.

How the data were processed

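Total RNA from 14 cultures of Naumovozyma castellii was sequenced strand-specifically. The submitters' processing notes name Trim Galore, HISAT2 2.2.0, featureCounts 2.0.0 and DESeq2, with no role or order, and the genome build and annotation are not given in the sources used here. Spike-in RNA was added per the labels, and it was not analysed here. The deposited values are normalised read densities (a signal in reads per nucleotide): a read count per feature divided by a size factor of the library and by the feature length. This was tested on the values. In every library 100% of the values, multiplied by the feature length, were whole multiples of a single step within 0.001 reads, so whole reads were recovered. Size factors by the median of ratios over the 37 snoRNAs differed from the deposited ones by at most 0.0315 on the log2 scale, against 0.899 over the mRNAs and 0.924 over all features. The scaling set is thus inferred from the values, and a fold change under it is relative to the snoRNAs. The deposited table has 8602 lines for 8343 distinct features, since 257 tRNA and 2 rRNA lines repeat the coordinates of an earlier line and were left out. Lengths span introns, since the length equals end minus start plus 1 on all 8602 lines. Of 5599 mRNAs 5588 are in the RefSeq table of gene names, 5586 with the same coordinates, and 4484 have a symbol. No CUT, XUT or SUT of 2390 overlaps an mRNA on the same strand. CUTs and XUTs overlap each other, so their values are not independent.

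Recovered reads per library ranged from 7895089 to 22437334. Groups were taken from the sample titles. Tests were run in R 4.3.3 with limma 3.58.1 and statmod 1.5.0 on log2(density + 0.02), where 0.02 is close to the 10th percentile of values above 0 (0.01601), so fold changes of low features are understated. All 14 libraries entered 1 model with 5 group means, leaving 9 residual degrees of freedom and a median of 7.69 prior degrees of freedom. eBayes was run with a trend and robust. A feature was tested if its mean density reached the pseudocount, which left 7518, and called at a Benjamini-Hochberg adjusted p under 0.05. Lists of genes, named by their S. cerevisiae symbols, were fixed before the data were examined. Of 18 lists 17 were tested: NMD factors, documented NMD targets, decapping and 5′ decay, exosome, ribosomal proteins (a rule on names that also takes RPP1), ribosome biogenesis, amino acid biosynthesis, sulphur amino acids, chaperones, general stress, histones, proteasome, iron regulon, glycolysis, respiration (with mitochondrially encoded genes), mating type, and silent information. None of the 2 RNA interference genes was found by name. Lists and classes were tested with camera at a preset correlation of 0.01 and again with an estimated one, and with fry.

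The rule for naming features was fixed before the data were examined. Per comparison, among called features whose libraries do not overlap between the groups and whose mean in the higher group reaches the class median, it takes the 10 mRNAs and 3 non-coding features with the largest change each way, up to 4 called members per list, and for the interaction the 3 largest each way. The text names part of what the rule takes. Features that turn direction under another scaling were left out of the text after those results were seen, and the closing section counts them.

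The replicate numbers come from the titles. Deviations from the group means of WT and upf1 libraries with the same number correlated at 0.365, 0.432, 0.209 and 0.354, so the numbers were taken as pairing the samples, although 3 of 8 libraries correlated best with their own number. Replicates 1 and 2 deviated together and apart from 3 and 4 (mean correlation 0.364 within and −0.362 across). Within these batches WT 1 correlated at 0.400 with upf1 2, and WT 4 at 0.489 with upf1 3, each above its own number. A pairing by number is thus not shown apart from the batches, and the replicate block assumes it. The treated and dcr1 upf1 groups have replicates 1 and 2 alone. Alternatives were other pseudocounts, other filters, centring, quantile normalization, the compared groups alone, the replicate block and leaving out each library. mRNA-ratio scaling, a batch term, voom on the recovered reads and replicates 1 and 2 alone were added after the data were seen, as were centring and the replicate block for the counts of higher mRNAs, CUTs and XUTs in upf1.

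The procedure was tested on simulated data with 200 of 7518 features changed, up or down, in 1 group. All features were given 1 dispersion, and no batches were simulated. The data hold batches, and in several comparisons most features change 1 way, so these rates may not carry over to them. For upf1 against WT it recovered 47.8% of 1.5-fold, 80.6% of 2-fold and 87.9% of 4-fold changes with 8 false calls. For upf1 CHX against WT CHX the shares were 19.4%, 68.7% and 81.8% with 12 false calls, and for the interaction 10.4%, 52.2% and 83.3% with 3. For dcr1 upf1 against upf1 they were 37.3%, 77.6% and 84.8% with 1 false call.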

Results

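Strand-specific total RNA-seq was made from the budding yeast Naumovozyma castellii, a relative of Saccharomyces cerevisiae that has kept RNA interference. The 14 libraries fall into 5 groups: wild type (WT, 4 libraries), cells without Upf1, the helicase at the centre of nonsense-mediated decay (NMD) (upf1, 4 libraries), WT and upf1 cells treated with the translation inhibitor cycloheximide (WT CHX and upf1 CHX, 2 libraries each), and cells lacking both Upf1 and the RNA interference nuclease Dicer (dcr1 upf1, 2 libraries). Cultures were grown at 25 °C, and cycloheximide was given at 100 µg/mL for 15 min. The deposited values are normalised read densities for 8343 distinct features, among them 5599 protein-coding genes (mRNAs), 1279 cryptic unstable transcripts (CUTs, substrates of the nuclear exosome in S. cerevisiae), 965 Xrn1-sensitive unstable transcripts (XUTs, substrates of the cytoplasmic 5′ exonuclease), 146 stable unannotated transcripts (SUTs), 37 snoRNAs and 302 tRNAs. Recovered reads per library ranged from 7895089 to 11172687 in WT, from 8022819 to 16411146 in upf1, from 13509980 to 14220444 in WT CHX, from 18994438 to 21111295 in upf1 CHX and from 18457571 to 22437334 in dcr1 upf1. Replicates are libraries that the labels list separately, and the p-values of single features in limma measure the spread between these libraries. Camera at its preset correlation, the Fisher test and the placement of calls along chromosomes set features against other features. Their p-values do not measure that spread.

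NAM7, the gene for Upf1 (NCAS_0A07730, chromosome 1, 1536668 to 1539646, minus strand; the genome build is not given in the sources used here), was read in all WT libraries and in none without Upf1. Its density was 0.522 ± 0.0710 (SD, n = 4) in WT and 1.18 ± 0.0203 (SD, n = 2) in WT CHX, from 1601, 1279, 1074 and 1474 reads and from 2584 and 2335 reads. All 8 libraries of the upf1, upf1 CHX and dcr1 upf1 groups held 0 reads. Against a floor of 3 counts over the group, NAM7 was at least 2219-fold lower in upf1 than in WT, at least 2053-fold lower in dcr1 upf1 than in WT and at least 2657-fold lower in upf1 CHX than in WT CHX. These floors cover counting error only. No feature could be paired with the names DCR1 or AGO1, so the second deletion was not checked here by name.

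**Figure D1:**
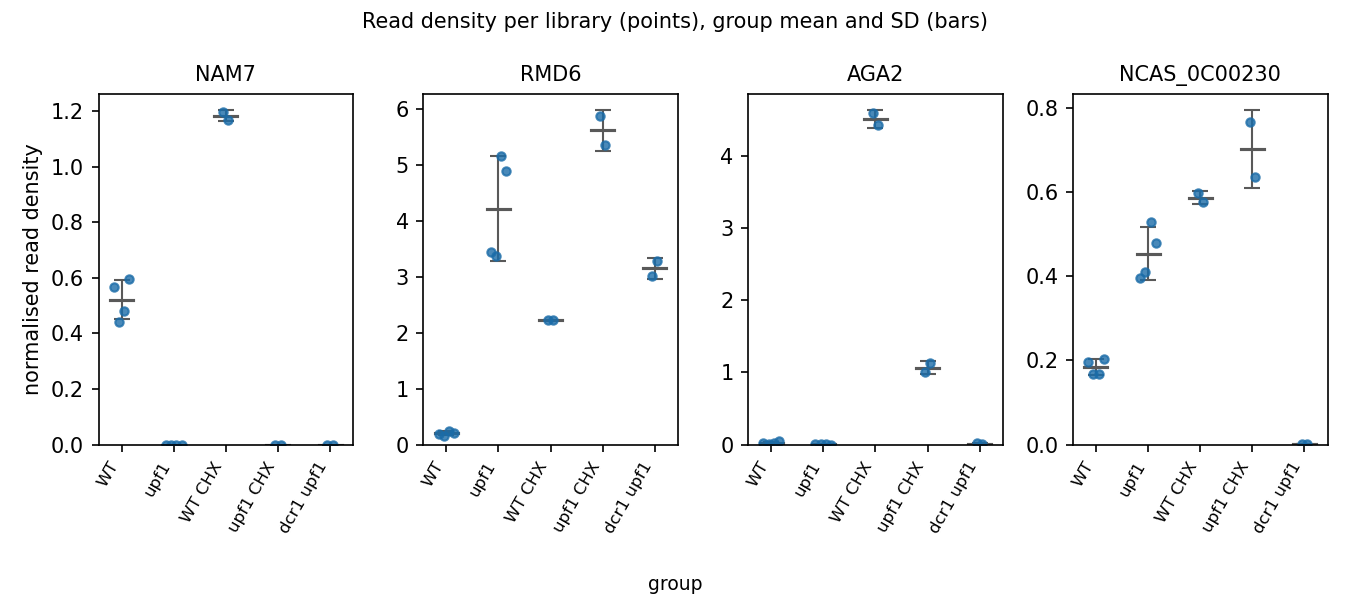
Normalised read density (reads per nucleotide after scaling by the authors) of NAM7, RMD6, AGA2 and NCAS_0C00230 in each of the 14 libraries, by group. Points are libraries, and bars give the group mean and SD. NAM7 is at 0 in all 8 libraries without Upf1, and RMD6 stands at 0.203 in WT and 4.22 in upf1 on average.

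The first comparison asks which RNAs change when NMD is lost. Transcripts rose far more often than they fell in upf1. The largest rise among protein-coding genes was that of RMD6, needed for sporulation, whose density went from 0.203 ± 0.0351 in WT to 4.22 ± 0.940 in upf1 (SD, n = 4 each; log2 fold change 4.23, SE 0.15; chromosome 10, 104201 to 104785). It was followed by NCAS_0J00100 (3.81), TAH1 (3.68; an Hsp90 cofactor), SLO1 (3.67), MAK31 (3.62; a subunit of an N-terminal acetyltransferase), ISC10 (3.44; needed for spore formation), TVS1 (3.34), NCAS_0D01620 (3.28), NCAS_0G02790 (3.27) and NCAS_0H03640 (3.23). SLO1 and ISC10 are neighbours on chromosome 2, as are TAH1 and TVS1 on chromosome 4. Falls were small: apart from NAM7 the named ones were NCAS_0J00860 (−0.81), NCAS_0B01090 (−0.53), the arginase gene CAR1 (−0.52), ICT1 (−0.43), ALD4 (−0.39; mitochondrial aldehyde dehydrogenase), NCAS_0B06070 (−0.36), FAS2 (−0.35; fatty acid synthase), PRB1 (−0.33; a vacuolar protease) and, among non-coding features, the tRNA NCAS_0Btrna12K (−0.42). Limma with Benjamini-Hochberg adjustment, over 7518 features, called 3042 higher and 44 lower (73 lower without upf1 replicate 3), of which 1167 and 2 changed at least 2-fold. With the replicate block 3400 were higher and 91 lower, and with the compared groups alone 2698 and 24. The deposited scaling gives the mRNAs a median log2 fold change of 0.20. With size factors taken over the mRNAs (mRNA-ratio scaling) 2250 were higher and 1791 lower, with centred libraries 1630 and 3254, and with quantile normalization 1575 and 2598. Within replicates 1 and 2 alone 2781 were higher and 327 lower. RMD6 stood 3.94 and TAH1 3.39 above the mRNAs under mRNA-ratio scaling. Some of the small falls rest on single libraries: without WT replicate 1 the calls of ALD4 (−0.28), FAS2 (−0.24) and PRB1 (−0.23) were lost, as was that of FAS2 without WT replicate 2 (−0.33), those of PRB1 without upf1 replicate 2 (−0.30) and without upf1 replicate 3 (−0.30), and those of NCAS_0Btrna12K without WT replicate 3 (−0.31) and without upf1 replicate 2 (−0.37). The calls of FAS2 and PRB1 were also lost when the compared groups were fitted alone (−0.35 and −0.33).

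Genes that are documented NMD targets in S. cerevisiae rose in upf1. Of 13 measured, 10 rose and none fell (10 when adjusted over the list alone), with a median log2 fold change of 1.45 (1.15 under mRNA-ratio scaling), led by the telomerase genes EST1 (2.35), EST3 (2.17) and EST2 (2.10) and the magnesium transporter gene ALR1 (1.80). The other members had log2 fold changes of −0.17 (SPT10), −0.03 (PPR1) and 0.09 (FZF1), and these 3 were singled out after their values were seen. Under mRNA-ratio scaling 10 members were higher and 3 lower, and these 3, SPT10 (−0.41), PPR1 (−0.32) and FZF1 (−0.22), passed as lower. Among 6 genes for NMD factors, 4 rose (5 adjusted over the list alone) and NAM7 fell, with NMD4 at 1.59, the casein kinase gene HRR25 at 1.5, EBS1 at 0.84 and, chosen after its value was seen, UPF3 at 0.78. Camera with its preset correlation set the NMD targets apart from the other features (limma, adjusted p = 0.000138; 0.987 with an estimated correlation). With a correlation estimated from these libraries no list call held in any comparison, and for upf1 against WT the adjusted p = 0.987 with an estimated correlation for every list but respiration (adjusted p = 0.993 with an estimated correlation).

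Amino acid, sulphur amino acid, respiration and mating genes are given next, and camera did not set these 4 lists apart (limma, adjusted p = 0.797 for amino acid biosynthesis, 0.63 for sulphur amino acids, 0.976 for respiration and 0.716 for mating). Over all features 3042 of 7518 were higher. In amino acid biosynthesis 23 of 51 rose and none fell (24 adjusted over the list alone), with LYS5 at 2.27, ARG8 at 2.03, SER33 at 1.99 and CPA1, for the arginine-specific carbamoyl phosphate synthetase, at 1.62. The list's median was 0.24 and turned to −0.08 under mRNA-ratio scaling, with 12 members higher and 12 lower. In sulphur amino acid metabolism 11 of 19 rose and 1 fell (11 and 1 adjusted over the list alone), with MET16 at 2.03, the sulphate permease gene SUL2 at 1.56, MET3 at 1.42 and MET10 at 0.99 (8 higher and 5 lower under mRNA-ratio scaling). The member that fell, MUP1 (−0.40), was chosen after its value was seen, and its call was lost without WT replicate 1 (−0.38), WT replicate 4 (−0.32), upf1 replicate 1 (−0.30) or upf1 replicate 2 (−0.29), with the compared groups alone (−0.40) and with no trend or robust fit (−0.40). Respiration genes rose in 23 of 51 cases (24 adjusted over the list alone), with SDH6 at 1.11 and COX16 at 0.91, and the median of 0.26 turned to −0.04 under mRNA-ratio scaling, where 3 were higher and 2 lower. Of 12 genes for mating type and haploid identity 7 rose, among them HO (1.96; the mating-type endonuclease), STE2 (1.74; the α-factor receptor), BAR1 (1.07; the α-factor protease) and STE6 (0.92; the a-factor exporter), and under mRNA-ratio scaling 5 were higher and 3 lower.

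In each of the remaining lists most members did not pass under the deposited scaling. Of 108 cytosolic ribosomal protein genes 3 rose (3 adjusted over the list alone), RPL22B (1.54), RPS14B (0.58) and RPL28 (0.47). Under mRNA-ratio scaling RPL28 no longer passed (0.14), and with centred libraries neither RPL28 nor RPS14B (0.12) did. The median of this list was −0.02 under the deposited scaling and −0.34 under mRNA-ratio scaling, where 2 were higher and 96 lower, and camera placed it below the other features (limma, adjusted p = 7.23e-12; 0.987 with an estimated correlation). Ribosome biogenesis genes had a median of −0.05 and camera also placed them below the rest (limma, adjusted p = 1.44e-10; 0.987 with an estimated correlation). Its 2 higher members of 67 (0 adjusted over the list alone), RRP8 (0.60) and BUD21 (0.52), were chosen after their values were seen. Without WT replicate 2 their log2 fold changes were 0.50 and 0.39, without upf1 replicate 3 they were 0.40 and 0.38, without upf1 replicate 4 they were 0.50 and 0.46, and without WT replicate 1 they were 0.61 and 0.48, and neither passed in any of these. RRP8 was also lost without WT replicate 3 (0.61), with voom (0.60) and with replicates 1 and 2 alone (0.29). Both were lost with the compared groups alone (0.60 and 0.52), with centring (0.14 and 0.05), with quantile normalization (0.17 and 0.07) and under mRNA-ratio scaling (0.29 and 0.21). Of 24 chaperone genes 4 rose (3 adjusted over the list alone), with BTN2 at 1.26, SSA3 at 1.13 and HSP104 at 0.62, and of 21 general stress genes 6 rose (6 adjusted over the list alone), with YGP1 at 1.42 and DCS2 at 1.05. In the iron regulon 2 of 13 rose, FRE6 (1.07) and the heme oxygenase gene HMX1 (0.91). One gene each rose in the proteasome list (RPN13, 0.59, of 34), in the exosome list (of 17; 0 adjusted over the list alone) and among silent information genes (SIR2, 0.59, of 3), 2 of 14 rose in decapping and 5′ decay (1 adjusted over the list alone; DCP1 at 0.65), and 0 of 13 glycolysis genes passed. With centred libraries and with quantile normalization the calls of SIR2 (0.13 and 0.13), DCP1 (0.19 and 0.19) and HSP104 (0.16 and 0.15) were lost. Under mRNA-ratio scaling 0 ribosome biogenesis genes were higher and 31 lower, 3 and 15 chaperone genes, 4 and 5 stress genes, 2 and 6 iron genes, 1 and 27 proteasome genes, 0 and 9 exosome genes, 1 and 9 decapping and 5′ decay genes, 0 and 8 glycolysis genes, 0 and 7 histone genes and 1 and 1 silent information genes. Camera placed exosome genes (limma, adjusted p = 0.0205), proteasome genes (0.00271), glycolysis genes (0.0033) and histone genes (0.0192) below the other features, and none of these passed with an estimated correlation (0.987 each). Of 8 histone genes HHO1 fell (−0.41; 0 adjusted over the list alone; chosen after its value was seen). Its call was lost without WT replicate 1 (−0.35), WT replicate 2 (−0.41), WT replicate 3 (−0.33), upf1 replicate 1 (−0.36), upf1 replicate 2 (−0.39) or upf1 replicate 3 (−0.38), and with the compared groups alone (−0.41).

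Called features in upf1 are given next by class. Of 768 XUTs 594 were higher and 1 lower, with a median log2 fold change of 0.85, and of 852 CUTs 438 were higher and 1 lower, with a median of 0.51. Of 5446 mRNAs 1970 were higher and 36 lower, with a median of 0.20, and of 117 SUTs 16 were higher. The overlapping transcripts CUT0698 (3.30) and XUT0541 (3.27) on chromosome 4 and CUT1114 (3.21) on chromosome 8 rose most. Under mRNA-ratio scaling 539 XUTs were higher and 11 lower, 360 CUTs were higher and 20 lower, 1334 mRNAs were higher and 1686 lower, 6 SUTs were higher and 28 lower, 11 tRNAs were higher and 23 lower, and 0 snoRNAs were higher and 21 lower. XUTs held 0.683 ± 0.0349% of reads in WT and 1.24 ± 0.0601% in upf1, and CUTs 0.256 ± 0.00789% and 0.472 ± 0.0162% (SD, n = 4 each; exact permutation test, 2-sided p = 0.0286 for each, the smallest this design allows; Benjamini-Hochberg adjusted p = 0.114). Camera in limma with its preset correlation placed XUTs (adjusted p = 4.63e-15) and CUTs (0.0334) above the other features and mRNAs (0.0195) below. With an estimated correlation these did not pass (adjusted p = 0.0538 for XUTs, 0.461 for CUTs and 0.713 for mRNAs), while SUTs (0.0284), tRNAs (0.0207) and snoRNAs (0.00104) lay below. None of the 37 snoRNAs, which set the deposited scaling, was called under it, and 24 of 283 tRNAs were higher and 6 lower. CUTs and XUTs are not separate sets of reads: 323 of the 852 tested CUTs overlap a XUT on the same strand.

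**Figure D2:**
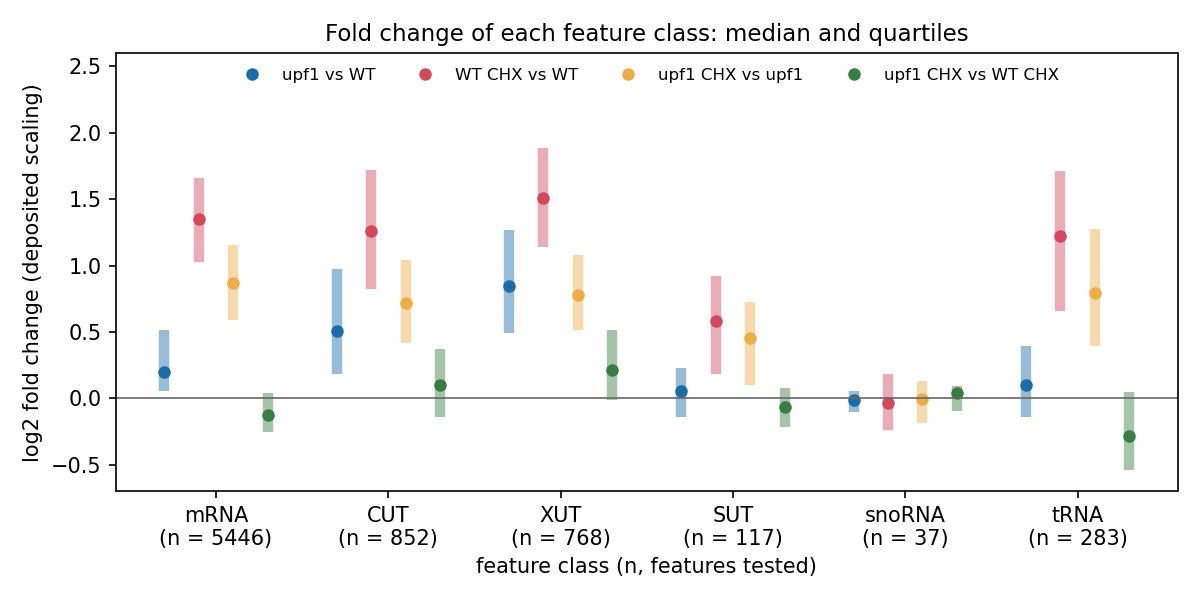
Median log2 fold change (points) and quartiles (bars) of each feature class under the deposited scaling, in the comparisons upf1 against WT, WT CHX against WT, upf1 CHX against upf1 and upf1 CHX against WT CHX, with the number of features tested under each class. The XUT median is 0.85 in upf1 against WT, the mRNA median is 1.35 in WT CHX against WT, and the snoRNAs lie near 0 in each comparison.

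Protein-coding genes with a CUT, XUT or SUT on the opposite strand were compared with the others. In upf1 against WT 46.5% of 1224 such genes were higher, against 33.2% of 4222 others, with median log2 fold changes of 0.27 and 0.19. The difference did not pass (camera in limma, adjusted p = 0.105, and adjusted p = 0.988 with an estimated correlation). In dcr1 upf1 against upf1 5 such genes were higher and 2 lower, against 8 and 4 others (camera, adjusted p = 0.254). Of 1092 CUTs, XUTs and SUTs opposite an mRNA 3 were higher and 2 lower, against 8 and 5 of 645 others (camera, adjusted p = 0.966). In dcr1 upf1 against WT only an overlap of at least 100 bases passed (camera, adjusted p = 0.0427, and 0.989 with an estimated correlation).

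Blocking translation raised nearly all mRNA densities in WT under the deposited scaling. AGA2, which encodes the binding subunit of a-agglutinin, rose most, from 0.0233 ± 0.0190 in WT to 4.51 ± 0.122 in WT CHX (SD, n = 4 and n = 2; log2 fold change 6.81, SE 0.33). HOR7 (5.01), ARO10 (4.56; phenylpyruvate decarboxylase), SPO24 (4.46), DIC1 (4.20; the mitochondrial dicarboxylate carrier), AAT1 (4.16; aspartate aminotransferase), NCAS_0G02180 (4.03), the amino acid permease genes DIP5 (3.96) and PUT4 (3.89) and NCAS_0A10640 (3.94) followed. The overlapping CUT0315 (4.55) and XUT0250 (4.53) and XUT0080 (4.28) rose, while CUT0750 (−1.17) and the overlapping XUT0165 (−1.47) and CUT0214 (−1.35) fell. Limma called 7075 features higher and 11 lower (17 lower without WT replicate 2), 5515 and 4 of them at least 2-fold. The median mRNA log2 fold change was 1.35, so changes are also given relative to the mRNAs: mRNA-ratio scaling gave 2656 higher and 1529 lower, centred libraries 1374 and 2587, and quantile normalization 1533 and 1691. AGA2 stood 5.70 above the mRNAs, HOR7 3.75, ARO10 3.39 and PUT4 2.54. The calls of XUT0165 and CUT0214 were lost without WT CHX replicate 1 (−1.45 and −1.35) and without WT CHX replicate 2 (−1.5 and −1.35) and with the compared groups alone (−1.47 and −1.35), and that of CUT0214 with voom (−1.5). Treated groups hold replicates 1 and 2 alone, and within those replicates 7184 features were higher and 25 lower.

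Gene lists are given next by their values after cycloheximide in WT, followed by the camera test against the other features. All 8 histone genes rose, with a median log2 fold change of 1.94 (0.58 under mRNA-ratio scaling, where 6 were higher and 2 lower), and HTA1 at 2.37, HTB1 at 2.18, HHF1 at 2.11 and HHT1 at 2.07. The 13 iron regulon genes rose (median 1.81, 0.45 relative to the mRNAs), led by HMX1 (3.28), the iron regulator gene AFT2 (2.35), SMF3 (1.96) and FET4 (1.94). Of 12 mating genes 11 rose (median 1.83, 0.49 relative to the mRNAs), with STE2 at 3.04, STE6 at 2.85 and BAR1 at 2.62. The 13 documented NMD targets rose (median 1.76, 0.46 relative to the mRNAs, with 9 higher and 0 lower), with CPA1 at 2.31, EST2 at 2.10, TEN1 at 2.05 and EST1 at 2.01. Of 108 ribosomal protein genes 105 rose, with a median of 0.68 that lay at −0.69 under mRNA-ratio scaling, where 4 were higher and 97 lower, although RPL22B (2.22) and RPS9A (2.14) rose above the typical mRNA. Of 24 chaperone genes 18 rose (17 adjusted over the list alone), with a median of 0.58 that lay at −0.78 under mRNA-ratio scaling, where 1 was higher and 21 lower. Camera in limma separated the NMD targets (adjusted p = 0.0104), ribosomal protein genes (0.000509), ribosome biogenesis genes (0.00125) and chaperone genes (1.36e-05) from the other features, the latter 3 downward. The histone genes did not pass (adjusted p = 0.106, 0.0614 with the replicate number as a block), nor did the iron (0.12) and mating genes (0.0751) without the block. With an estimated correlation none of these lists passed (adjusted p = 0.915 for each). With the block the ribosome biogenesis genes turned from below (adjusted p = 0.00125) to above (0.0188) the other features, the call of the ribosomal protein genes was lost (adjusted p = 0.185), and calls appeared for mating genes (0.00409), iron genes (0.0356), the proteasome (0.074 and 0.0312, below) and glycolysis (0.074 and 0.0188, below), and for the exosome and amino acid biosynthesis lists (0.0312 each, above).

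By class, 5344 of 5446 mRNAs, 741 of 768 XUTs, 735 of 852 CUTs and 189 of 283 tRNAs were higher after cycloheximide in WT, with medians of 1.35, 1.51, 1.26 and 1.22. Of 117 SUTs 63 were higher (median 0.58), and camera placed them below the other features (limma, adjusted p = 1.91e-36; 0.000227 with an estimated correlation). The snoRNAs were centred at −0.04 with 3 higher and 3 lower of 37. Under mRNA-ratio scaling 1845 mRNAs were higher and 1350 lower, 467 and 20 XUTs and 314 and 52 CUTs. For tRNAs the numbers were 22 and 26, for SUTs 8 and 44 and for snoRNAs 0 and 31. The medians under that scaling were 0.07 for mRNAs, 0.63 for XUTs, 0.37 for CUTs, 0.10 for tRNAs and −0.38 for SUTs. CUTs thus lay below the mRNAs under the deposited scaling and above them under this one. The share of reads held by snoRNAs was 7.27 ± 0.758% in WT (SD, n = 4) and 3.96 ± 0.0283% in WT CHX (SD, n = 2), for which the exact permutation test gave p = 0.0667, the smallest possible with 4 against 2.

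Cycloheximide also raised most mRNA densities in upf1 cells. AGA2 (5.33), AAT1 (4.20), DIC1 (4.19), SPO24 (4.16), PUT4 (4.09), NCAS_0A10640 (3.78), DIP5 (3.74), PAR32 (3.50), ACS1 (3.34; acetyl-CoA synthetase) and DPI8 (3.27) had the largest rises, and CUT0315 (4.79) and XUT0250 (4.77) led the non-coding ones. RGI1 (−1.52), NCAS_0H01880 (−0.56), NCAS_0C03020 (−0.53), NCAS_0A14630 (−0.44), XUT0165 (−1.92), CUT0214 (−1.76) and CUT0750 (−1.04) fell. The 8 histone genes rose (median 1.63, 0.65 relative to the mRNAs), with HHT1 at 1.90, HHF1 at 1.85, HTA1 at 1.84 and HTB1 at 1.78, and 12 of 13 iron genes rose (13 adjusted over the list alone), with HMX1 at 2.53, AFT2 at 1.93, ISU1 at 1.92 and SMF3 at 1.52. Of 24 chaperone genes 11 rose (10 adjusted over the list alone), and their median of 0.33 turned to −0.64 under mRNA-ratio scaling. The 13 NMD targets all rose (median 0.67), but their median under mRNA-ratio scaling was −0.30, with 2 higher and 8 lower. Limma called 6342 features higher and 18 lower (11 lower without upf1 CHX replicate 2), 2560 and 4 of them at least 2-fold, and 6865 and 44 within replicates 1 and 2 alone. The median mRNA log2 fold change was 0.86. Relative to the mRNAs 1383 features were higher and 1901 lower, with centred libraries 1176 and 2300, and with quantile normalization 1378 and 1557. By class 4945 mRNAs (median 0.86), 626 XUTs (0.78), 585 CUTs (0.72) and 52 SUTs (0.46) rose. Under mRNA-ratio scaling 1156 mRNAs were higher and 1634 lower, 113 and 100 XUTs, 88 and 83 CUTs and 5 and 34 SUTs. The medians were then −0.06 for mRNAs, 0.04 for XUTs, −0.01 for CUTs and −0.23 for SUTs. The order of mRNAs, XUTs and CUTs thus depended on the scaling. Camera separated the histone genes (adjusted p = 0.00572) and, downward, the chaperone genes (0.000103), with adjusted p = 0.811 with an estimated correlation. With the block, calls appeared for iron genes (0.0188), mating genes (0.00547), the exosome (0.00213), ribosome biogenesis (7.13e-05, upward) and stress genes (0.0287, downward), against 0.148, 0.165, 0.148, 0.165 and 0.405 without it, where ribosome biogenesis pointed downward. NCAS_0C03020 was lost with the block (−0.25), with replicates 1 and 2 alone (−0.20) and without upf1 replicate 3 (−0.41), upf1 replicate 4 (−0.43), upf1 CHX replicate 1 (−0.55) or upf1 CHX replicate 2 (−0.51). NCAS_0A14630 was lost with a term for the replicate batches (−0.28), with replicates 1 and 2 alone (−0.16), with the compared groups alone (−0.44) and without upf1 replicate 3 (−0.36), upf1 replicate 4 (−0.33) or upf1 CHX replicate 2 (−0.32).

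Fewer features were called between treated upf1 and treated WT cells than between upf1 and WT. The treated comparison has 2 libraries against 2, and in simulated data it recovered 19.4% of 1.5-fold changes, against 47.8%. With the compared groups alone 802 were higher and 1098 lower, against 2698 and 24 in upf1 against WT. NCAS_0G02790 (2.27), NCAS_0J00100 (2.23), TAH1 (1.75), SLO1 (1.68), ISC10 (1.63), the allantoin genes DAL3 (1.61) and DAL5 (1.5), REC107 (1.57; meiotic recombination), NCAS_0B04430 (1.48) and NCAS_0F04110 (1.44) were higher in upf1 CHX, as were XUT0758 (1.84), CUT0325 (1.83) and CUT0327 (1.89). AGA2 was lower, at 1.06 ± 0.0902 in upf1 CHX and 4.51 ± 0.122 in WT CHX (SD, n = 2 each; log2 fold change −2.06, SE 0.38), as were NCAS_0A12750 (−1.69), NCAS_0G01570 (−1.20), the pseudouridine synthase gene CBF5 (−1.20), PAI3 (−1.18), NCAS_0J00860 (−1.09), the elongation factor genes CTR9 (−1.06) and SPT5 (−1.04), FUN12 (−1.04; translation initiation), NCAS_0Dtrna3E (−1.33), XUT0667 (−1.31) and SUT069 (−1.17). Of 13 NMD targets 4 rose (8 adjusted over the list alone): EST3 (0.99), EST1 (0.81), EST2 (0.70) and REV7 (0.59). Of 51 amino acid biosynthesis genes 4 rose, ARG8 (1.00), ARG3 (0.89), LYS5 (0.88) and SER33 (0.76), and MET16 (0.96), BTN2 (0.82) and RPL22B (0.80) rose in their lists. Of 12 mating genes AGA2 and STE6 (−0.67) fell (3 adjusted over the list alone).

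Limma called 321 features higher and 74 lower in upf1 CHX against WT CHX, 116 and 23 at least 2-fold, and with the replicate block 578 and 324. With the compared groups alone 802 were higher and 1098 lower, and with replicates 1 and 2 alone 801 and 889, so more were lower in these fits. Of 768 XUTs 81 were higher and 2 lower (median 0.22), of 852 CUTs 45 and 1, and of 5446 mRNAs 193 and 66 (median −0.13), against 133 and 4, 73 and 0, and 449 and 385 under mRNA-ratio scaling. Under mRNA-ratio scaling 658 features were higher and 395 lower, under centring 761 and 525, and under quantile normalization 669 and 470. Without upf1 CHX replicate 1 there were 99 higher and 21 lower, without WT CHX replicate 1 there were 128 and 18, without WT CHX replicate 2 there were 178 and 21, and without upf1 CHX replicate 2 there were 209 and 16. Camera set NMD targets above the other features (adjusted p = 0.000409) and ribosome biogenesis (0.00019), ribosomal protein (0.000456), proteasome (0.00998), histone (0.027), exosome, stress, iron and mating genes (0.0457 each) below, with adjusted p = 0.733 with an estimated correlation for each. The mating call was lost with the block (adjusted p = 0.0609), as was that of NCAS_0J00860 (−1.09). NCAS_0Dtrna3E no longer passed under mRNA-ratio scaling (−1.12), with centring (−1.28) or with voom (−1.54), and CBF5 did not with voom (−1.22). With a pseudocount 10 times smaller the calls of AGA2 (−2.08), CBF5 (−1.22), NCAS_0Dtrna3E (−1.58) and XUT0667 (−1.80) were lost.

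Many of these calls needed all 4 libraries. Without WT CHX replicate 1 the calls of AGA2 (−2.04), ARG3 (0.96), ARG8 (0.99), BTN2 (0.90), CBF5 (−1.21), CUT0327 (1.44), EST2 (0.71), MET16 (0.84), NCAS_0Dtrna3E (−1.30), NCAS_0J00860 (−1.17), REV7 (0.57), RPL22B (0.75), SER33 (0.81), STE6 (−0.66) and SUT069 (−1.24) were lost. Without WT CHX replicate 2 those of ARG3 (0.81), ARG8 (1.01), BTN2 (0.73), CBF5 (−1.18), EST1 (0.75), EST2 (0.69), NCAS_0Dtrna3E (−1.36), NCAS_0J00860 (−1.02), REV7 (0.61), SER33 (0.72), STE6 (−0.69) and SUT069 (−1.11) were lost. Without upf1 CHX replicate 1 those of AGA2 (−1.98), ARG3 (0.79), ARG8 (0.95), BTN2 (0.65), CBF5 (−1.29), CUT0327 (1.5), EST1 (0.74), EST2 (0.60), MET16 (0.85), NCAS_0Dtrna3E (−1.32), REV7 (0.53), RPL22B (0.77), SER33 (0.69), STE6 (−0.78) and SUT069 (−1.26) were lost. Without upf1 CHX replicate 2 those of ARG3 (0.98), CBF5 (−1.11), FUN12 (−0.90), SPT5 (−0.91), NCAS_0J00860 (−0.94), NCAS_0Dtrna3E (−1.33), REV7 (0.65), STE6 (−0.57) and SUT069 (−1.09) were lost.

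The response to cycloheximide was smaller in upf1 than in WT for nearly all features whose response differed. RMD6 went from 0.203 to 2.23 in WT and from 4.22 to 5.62 in upf1 on treatment (interaction on the log2 scale −2.91, SE 0.25), and NCAS_0G02180 from 0.398 to 6.78 in WT and from 2.11 to 3.48 in upf1 (−3.31, SE 0.18). The tRNA NCAS_0Htrna4F had an interaction of −2.57, and CUT0781, the feature with a larger response in upf1, one of 0.95. Of 13 NMD targets 10 had a smaller response in upf1 (10 adjusted over the list alone; median −1.0, −0.68 under mRNA-ratio scaling; camera in limma, adjusted p = 9.47e-06), as did 6 of 12 mating genes (7 adjusted over the list alone; median −0.75; 0.0479), 8 of 51 amino acid biosynthesis genes and 6 of 19 sulphur amino acid genes. Camera placed ribosomal protein (8.57e-07), ribosome biogenesis (9.28e-05) and glycolysis genes (0.0479) above the other features, and for each list adjusted p = 0.944 with an estimated correlation. The calls of ribosome biogenesis (0.0745) and glycolysis (0.0593) were lost with the block. Limma called 1 interaction higher and 1609 lower, 0 and 745 at least 2-fold, and with the block 9 and 2419. Among the classes 285 XUTs, 194 CUTs and 1112 mRNAs had a smaller response in upf1, and 219, 125 and 661 under mRNA-ratio scaling, where 35 mRNAs had a larger one. The mRNA median was −0.38, and under mRNA-ratio scaling 39 features were higher and 1009 lower, with centred libraries 433 and 600, and with quantile normalization 105 and 525. Without upf1 CHX replicate 2 the lower interactions numbered 733 and without WT CHX replicate 2 they numbered 861. The single higher one became 0 without WT replicate 3, upf1 CHX replicate 1 or upf1 CHX replicate 2, 2 without upf1 replicate 1 and 3 without upf1 replicate 4. NCAS_0Htrna4F was lost under mRNA-ratio scaling (−1.97), with centring (−2.05), with quantile normalization (−1.57), with a pseudocount 10 times smaller (−5.42), without WT CHX replicate 2 (−2.20), without upf1 CHX replicate 1 (−2.31) and without upf1 CHX replicate 2 (−2.83). CUT0781 was lost under mRNA-ratio scaling (0.99), with a pseudocount 10 times smaller (1.40), with voom (1.25), with the compared groups alone (0.95), with replicates 1 and 2 alone (0.48) and without WT replicate 3 (0.85), WT replicate 4 (0.84), upf1 replicate 1 (0.97), upf1 replicate 3 (0.88), upf1 replicate 4 (0.92), WT CHX replicate 1 (0.83), WT CHX replicate 2 (1.07), upf1 CHX replicate 1 (0.71) or upf1 CHX replicate 2 (1.19).

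Features higher in upf1 were compared with those higher after cycloheximide in WT. Of the 3042 and 7075 features, 3016 were higher in both, against 2863 for independent lists of these sizes. Relative to the mRNAs 1454 were higher in both, against 795 for independent lists, and 909 were lower in both, against 364. Both comparisons share the WT libraries. Unchanged groups simulated against them gave, over 50 draws, a mean covariance of the log2 fold changes of 0.0165, against 0.137 observed, a difference of 0.120. Their correlation was 0.389 observed and 0.413 in these draws on average. With the WT libraries split between the comparisons the covariance was 0.0900 and 0.118, and 2757 and 2572 features were higher in both, against 2625 and 2461 for independent lists.

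The dcr1 upf1 and upf1 libraries differed in few features. The protein-coding genes NCAS_0G04260 (2.38), NCAS_0H01520 (1.95), NCAS_0H03670 (1.84), NCAS_0H03380 (1.83), NCAS_0H03660 (1.67), NCAS_0A09630 (1.51) and NCAS_0B02340 (1.25) were among those higher in dcr1 upf1 than in upf1, with XUT0431 (2.38), XUT0242 (2.31) and XUT0908 (2.12). NCAS_0F04110 fell from 1.08 ± 0.0460 in upf1 (SD, n = 4) to 0.20 ± 0.00675 in dcr1 upf1 (SD, n = 2; log2 fold change −2.32, SE 0.12), and NCAS_0A05800 (−1.41), NCAS_0J00100 (−1.03), the overlapping CUT0544 (−2.40) and XUT0407 (−2.28) on chromosome 2 and CUT0324 (−1.29) also fell. NCAS_0C00230 (chromosome 3, 25138 to 26970), singled out after its values were seen, had 1011, 1123, 744 and 554 reads in upf1 and 4 reads in each dcr1 upf1 library, with mean densities of 0.454 and 0.00112 (log2 fold change −4.48). Limma called 25 features higher and 13 lower (8 lower without dcr1 upf1 replicate 2), 22 and 10 at least 2-fold, comprising 13 higher and 6 lower mRNAs, 2 and 4 CUTs, 9 and 3 XUTs and 1 tRNA. Voom on the recovered reads called 46, and 875 features had an unadjusted p under 0.05. Under mRNA-ratio scaling 41 were higher and 11 lower, and 89 features were called when replicates 1 and 2 of every group were used alone. No member of any list was called (limma; 0 also when adjusted over the list alone). Camera placed ribosomal protein (adjusted p = 4.46e-12), ribosome biogenesis (5.46e-07), histone (0.0251) and exosome genes (0.0328) below the other features and stress genes above (3.9e-08), with adjusted p = 0.943 with an estimated correlation for each. With the block the exosome call was lost (0.567), and amino acid biosynthesis moved from 0.219 to 2.7e-05, downward.

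Against WT, most of the features that changed in dcr1 upf1 cells rose. Among the called genes with a symbol, RMD6 (3.84), SLO1 (3.43), MAK31 (3.40), TAH1 (3.35) and ISC10 (3.30) had the largest rises. NCAS_0E00690 (−1.90), NCAS_0J00860 (−1.5), NCAS_0A05800 (−1.41), CBF5 (−1.39), TIF4631 (−1.20; translation initiation), RPL35A (−1.17), RPL29 (−1.11) and RAM1 (−1.05; farnesyltransferase) fell. Of 13 NMD targets 10 rose (10 higher and 1 lower adjusted over the list alone; median 1.35; camera in limma, adjusted p = 0.000166, adjusted p = 0.827 with an estimated correlation), with EST1 at 2.16, EST3 at 2.02, EST2 at 1.94 and TEN1 at 1.61. Of 108 ribosomal protein genes 30 fell and 3 rose (25 and 3 adjusted over the list alone; median −0.31; 5.21e-20, 0.827 with an estimated correlation; 97 lower and 2 higher under mRNA-ratio scaling), RPL27B (−0.80) among those that fell. Camera also placed ribosome biogenesis (4.01e-15), exosome (0.00126), histone (0.00127) and proteasome genes (0.0045) below the rest, with adjusted p = 0.886, 0.909, 0.827 and 0.909 with an estimated correlation, and with the block glycolysis genes too (0.00302, against 0.0536 without). Limma called 2168 features higher and 247 lower, 1012 and 19 at least 2-fold. Of 768 XUTs 509 were higher and 3 lower (median 0.78), of 852 CUTs 329 and 4 (0.42), and of 5446 mRNAs 1310 and 232 (0.06). Under mRNA-ratio scaling more mRNAs were lower (1610) than higher (1346), with 529 and 6 XUTs and 348 and 17 CUTs. Under mRNA-ratio scaling 2239 were higher and 1663 lower, with centred libraries 1678 and 2632, and with quantile normalization 1482 and 2393. Within replicates 1 and 2 alone 2609 were higher and 569 lower. Without dcr1 upf1 replicate 2 the count was 1523. The lower calls numbered 43 without dcr1 upf1 replicate 1, 75 without dcr1 upf1 replicate 2, 373 without WT replicate 2 and 153 without WT replicate 4. RPL27B was lost without WT replicate 3 (−0.69), WT replicate 4 (−0.74), dcr1 upf1 replicate 1 (−0.80) or dcr1 upf1 replicate 2 (−0.80), RPL29 without WT replicate 4 (−1.07), dcr1 upf1 replicate 1 (−1.12) or dcr1 upf1 replicate 2 (−1.10), and RPL35A without dcr1 upf1 replicate 1 (−1.14) or dcr1 upf1 replicate 2 (−1.20).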

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

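Every test in this part was chosen after the results were seen, except the search for libraries that stand apart, the count of other splits of the libraries and the interaction test. Of 148 groups of 4 libraries examined, 7 had a library far from the others, and chance gives 5%. CUTs held 0.496% of reads in upf1 replicate 3, against 0.462 to 0.465% in the other upf1 libraries, and snoRNAs held 6.37% there, against 6.84 to 6.91%. The density of ICT1 was 1.02 in WT replicate 1, against 0.744 to 0.768 in the other WT libraries. EST2 stood at 0.117 in WT replicate 1, against 0.0917 to 0.0949, and at 0.590 in upf1 replicate 3, against 0.454 to 0.465. RPL28 stood at 45.5 in upf1 replicate 4, against 40.4 to 41.1, and HHO1 at 0.291 in upf1 replicate 4, against 0.208 to 0.220.

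By the interaction test in limma, the response to cycloheximide differed between WT and upf1 for 1610 features. The largest differences were those of NCAS_0G02180 (−3.31), RMD6 (−2.91), NCAS_0Htrna4F (−2.57) and, in the other direction, CUT0781 (0.95).

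The calls in upf1 against WT were set against other splits of the same 8 libraries. Only 1 of the 35 splits, the real one, gave as many calls (2722 with these libraries alone). The highest other, replicates 1 and 2 against 3 and 4, gave 367, so the batches show as a structure of the samples. This argues against chance but, with 35 splits, cannot exclude it. The other splits also mix WT with upf1 libraries, which widens their spread and lowers their calls. Of the 8 splits that part every pair of the same number the highest other gave 0, and 8 splits are too few to decide. Both groups hold replicates 1 to 4, so the batches are balanced between them. Calls made in the libraries of one batch were read in those of the other to see how far they repeat. This cannot test the batch as a cause, since each batch holds libraries of both groups. Of 2485 features called higher in replicates 1 and 2, 97.1% had a positive log2 fold change in replicates 3 and 4 (88.3% of the features not called higher), and of 3023 called in replicates 3 and 4, 96.0% did in replicates 1 and 2 (54.7%). Under mRNA-ratio scaling the shares were 94.2% (27.0%) and 99.0% (38.1%). The groups differ by the deletion of NAM7, which had 0 reads in all upf1 libraries. The design does not separate it from any other difference between the strains.

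The rise of most mRNAs after cycloheximide depends on what the scaling holds fixed. If the snoRNAs alone had fallen, the snRNAs, which are not in the scaling set, should rise with the mRNAs. Their median was −0.20 (−0.04, −0.20 and −0.53), against 1.35 for the mRNAs. The negative values rest on WT replicates 3 and 4. ENSRNA049639705 stood at 18.7, 17.3, 38.6 and 36.1 in WT replicates 1 to 4, and at 19.2 and 16.8 in WT CHX. ENSRNA049639701 stood at 194, 163, 250 and 295, and at 189 and 195. Against replicates 1 and 2 the snRNAs thus neither fell clearly nor rose with the mRNAs. A fall of snoRNAs and snRNAs together cannot be told apart from a rise of the mRNAs. The SUT median of 0.58 lies between, the tRNA median of 1.22 lies near that of the mRNAs, and no total RNA measure was analysed here. An effect of treatment on mRNA decay or synthesis may contribute and was not tested.

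Calls in dcr1 upf1 against upf1 lay near chromosome ends more often than other tested features, although most of the 38 did not. Within 10 kb of the outermost feature lay 15 of 38 calls (39.5%), against 1.66% of other tested features. These calls are not independent: XUT0972, CUT0324 and CUT0325 overlap, and others are neighbours. When the calls were turned along the ordered features, which keeps neighbours together, a share of 0.000935 of 7488 turns placed as many calls near the ends (highest other 16) and 0.0012 on as many as the observed 8 ends (highest other 10). This argues against chance placement. The replicate batches are argued against by 100% of these 15 passing with the same sign against upf1 replicates 1 and 2 alone. The lowest density among them, in the higher dcr1 upf1 library, was 18.9% of that in upf1. This argues against complete loss of these features, provided their reads are unique, but not against a change in copy number. Neighbours moved together. On chromosome 10 NCAS_0J00100, NCAS_0J00110 and XUT0972 stood at 49.8%, 31.8% and 37.9% of the upf1 density. On chromosome 5 NCAS_0E00100 and NCAS_0E00120 stood at 544% and 691%. Copy number at the ends was not tested. Loss of Dicer stays open, and so does any other difference between the strains, which the design does not separate from it.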

How the results depend on the processing

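mRNA-ratio scaling, the batch term, voom, replicates 1 and 2 alone, and centring and the block for the counts of higher mRNAs, CUTs and XUTs were chosen after the data were seen, and the other tests before. Of 164 alternatives of the counts, 114 stayed within 1.5 times, 39 moved and 11 changed which direction holds more calls. The XUT share of reads rose by 0.554 points in upf1 and the XUT share of density by 0.346, and the antisense difference of medians was 0.083 and, with an overlap of at least 100 bases, 0.091. The features named in the text are the steadier part of those the naming rule takes: features that turn direction under another scaling were left unnamed once that was known. Over all 361 results the rule takes, 6427 of 6893 alternatives kept direction and call, 347 lost the call and 119 turned direction. They turned in 39 features, none of them named, and 164 of the 361 are not named. Of these, 18 belong to WT CHX against WT and 17 to upf1 CHX against upf1, and 38 turned with centring, 33 with mRNA-ratio scaling and 24 with quantile normalization. In all, 124 of the 361 lost the call or turned in at least 1 alternative. Over the 206 named results, which include some chosen after their values were seen, 3798 of 3970 alternatives were the same, 160 lost the call, 6 gained it and 6 turned. FZF1 in upf1 against WT was −0.37 with centring, −0.37 with quantile normalization and −0.22 with mRNA-ratio scaling, and PPR1, which was not called, ranged from −0.12 to 0.063 with 1 library left out and was above 0 without WT replicate 4, upf1 replicate 1 or upf1 replicate 2.

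With centred libraries, the calls numbered 4884 for upf1 against WT, 3961 for WT CHX against WT, 3476 for upf1 CHX against upf1, 1286 for upf1 CHX against WT CHX, 1033 for the interaction and 4310 for dcr1 upf1 against WT. With quantile normalization they were 4173, 3224, 2935, 1139, 630 and 3875. With mRNA-ratio scaling WT CHX against WT gave 4185, upf1 CHX against upf1 3284, upf1 CHX against WT CHX 1053, the interaction 1048 and dcr1 upf1 against WT 3902. The cause was not tested. The mRNA median in upf1 against WT was 0.20 under the deposited scaling, −0.27 with centring, −0.16 with quantile normalization and −0.10 with mRNA-ratio scaling, and in dcr1 upf1 against WT 0.06, −0.21, −0.15 and −0.05. With a mean of at least 10 times the pseudocount, which leaves 4882 features, the calls were 1665 (upf1 against WT), 4691 (WT CHX against WT), 1001 (interaction), 20 (dcr1 upf1 against upf1) and 1243 (dcr1 upf1 against WT). At least 2-fold were 1169, 2564 (upf1 CHX against upf1), 139 (upf1 CHX against WT CHX), 745 and 1031. For upf1 CHX against WT CHX a 10 times larger pseudocount gave 998, the replicate block 902, the batch term 967, the compared groups alone 1900 (802 higher, 1098 lower) and replicates 1 and 2 alone 1690 (801 higher, 889 lower). The interaction gave 2428 with the block and 2667 with the batch term, and dcr1 upf1 against upf1 gave 89 with replicates 1 and 2 alone. The cause was not tested for these fits. Leaving out 1 library gave 120 to 225 calls for upf1 CHX against WT CHX, 733 to 1880 for the interaction and 1523 to 2413 for dcr1 upf1 against WT. A lone library left in a group is assumed to vary like the other groups.

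The class calls numbered 50, and 20 with an estimated correlation, 26 with centring and 32 with mRNA-ratio scaling. Higher mRNAs, CUTs and XUTs in upf1 numbered 1015, 239 and 371 with centring. The list calls numbered 39, and 0 with an estimated correlation and 61 with fry under mRNA-ratio scaling; the cause was not tested. The call of NMD factors in the interaction (adjusted p = 0.0043 in limma) is not used, since the list holds NAM7, whose value the deletion fixes. The replicate block turned the ribosome biogenesis call in WT CHX against WT from downward to upward. The intron-containing genes were not run. Depth limits low features most in WT replicate 3, which has the fewest reads (7895089).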

Other observations

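All tests in this part were chosen after the results were seen. Features near chromosome ends rose more than others in upf1. Of 139 tested features within 10 kb of a chromosome's outermost feature, 99 were higher and 0 lower in upf1 against WT (71.2%, against 51.0% of other features matched by class and density; 59.7% against 41.4% under mRNA-ratio scaling), with a median log2 fold change of 0.90, above the highest median of 1000 matched draws (0.60). These draws take neighbouring features as independent. With neighbours kept together, by turning the values along the ordered features, 4 of 7488 turns gave a median as high, the observed one included. In upf1 CHX against WT CHX 33 of them were higher (23.7%, against 6.27% of matched features). In dcr1 upf1 against upf1 7 of the 15 calls were higher and 8 lower, on 6 chromosomes.

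Protein-coding genes without a symbol rose in upf1 more often. This set shares members with the features near chromosome ends, where 50 of the 78 tested mRNAs have no symbol. The 2 observations were not separated. The comparison below was not matched by density or position, and its Fisher test takes genes as independent. At least 2-fold higher were 25.7% of the 1014 tested mRNAs without a symbol and 8.73% of 4432 with one (Fisher exact odds ratio 3.62, 95% interval 3.03 to 4.33, p = 1.36e-43; 20.2% and 5.82% under mRNA-ratio scaling). The 131 tested mRNAs whose span is not a multiple of 3 had a median of 0.81 after cycloheximide in WT, against 1.36 for the others (−0.51 and 0.08 under mRNA-ratio scaling). Camera placed them below the other mRNAs with its preset correlation (limma, adjusted p = 2.57e-06 over 7 comparisons), and with an estimated correlation they did not pass (adjusted p = 0.798). Of 7 tested mitochondrial mRNAs limma called 0 in upf1 against WT, 3 higher in WT CHX against WT (median 0.77) and 0 in upf1 CHX against upf1 (median 0.30), and at an unadjusted p under 0.05 the numbers were 0, 3 and 0.

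As a hypothesis, genes specific to a cells may respond to cycloheximide apart from other mating genes in WT. Relative to the mRNAs AGA2 stood at 5.70, STE2 at 1.84, STE6 at 1.55 and BAR1 at 1.49 in WT CHX against WT (median 1.70). The 6 other mating genes compared had a median of 0.13, which argues against a rise shared by these 6. HO, another member of the mating list, was not among them. Under the deposited scaling HO rose by 2.58, close to BAR1 (2.62), so a rise of this size was not limited to the 4 genes. In upf1 CHX against upf1 AGA2 stood at 4.48, but STE2 at −0.02, STE6 at 0.31 and BAR1 at 0.20 were no higher than GPA1 (0.37). In upf1 cells 3 of the 4 genes thus did not respond apart from the others. In upf1 against WT, untreated, STE2 (1.53), BAR1 (0.88) and STE6 (0.64) already stood above the mRNAs, and AGA2 (−0.77) did not. The 6 others ranged there from −0.50 (STE18) to 0.09 (STE4). Whether this higher start limited the response of the 3 genes was not tested. AGA2 was noticed first, so the comparison was made on the data that raised it.

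NCAS_0C00230 may be the gene deleted in dcr1 upf1, as a hypothesis. If it were one of many silenced genes, others should fall as far, but it is the 1 mRNA with an upf1 density of at least 0.1 that lay under 2% of it in both dcr1 upf1 libraries (0.212% and 0.284%). The sources used here do not pair this identifier with a name, so the hypothesis remains untested by identity.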
